A study of Homo sapiens with 9 samples.

How the data were processed

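RNA of HUVEC was sequenced as single-end reads in 9 libraries, in 3 groups of 3, with the groups and replicate numbers taken from the sample titles. Per the series design text, libraries were made from poly(A) RNA with a TruSeq RNA kit, which marks no strand. Per the labels' protocols and the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to GRCh38 with STAR 2.4.2a and counted with HTSeq 0.6.1 over the GENCODE 23 annotation. The authors deposited the resulting raw counts per gene symbol, not normalized, in 1 table with 28669 genes. The smallest total of a gene over the 9 libraries was 2, so genes with less are not listed. The strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. Reads of near-identical genes or of overlapping and antisense genes can therefore be lost or credited to a partner. The authors also ran DESeq2 and Cufflinks, per the series design text, and those results were not used here.

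Depth was 22544534 to 28590633 counts per library, so that the floor of 3 counts corresponds to 0.105 to 0.133 CPM. This floor and the counting intervals (95%) cover counting error only, since PCR copies are not independent molecules. Replicates of a group differed by 2.57 to 11.5 times the sampling noise (chi-square per degree of freedom), which does not show whether they came from separate cultures. Each library was entered as 1 replicate. The biological coefficient of variation was 0.0463.

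Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (15018) were scaled by TMM, and all 9 libraries were fitted together with 1 mean per group, with the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment. A gene was called at adjusted p under 0.05. Adjusted p-values of single genes come from this test and are two-sided. The 3 comparisons were simvastatin against vehicle with the control virus, the EZH2 virus against the control virus with simvastatin, and the EZH2 virus with simvastatin against the control virus with vehicle. CPM values use the TMM library sizes and are given as mean ± SD over 3 libraries. Standard errors are the log2 change divided by the square root of F.

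Before the data were examined, 26 gene lists and the rule for named genes were fixed, along with the design and most alternatives. The named genes were 12 fixed genes, the 8 largest increases and 8 largest decreases per comparison among called genes with a mean of at least 1 CPM, no overlap of the groups and a symbol that is not a clone name, up to 4 members of each list with the smallest adjusted p, and the 8 genes per direction called in both the first and second comparison with opposite signs whose smaller change was largest. The lists reported here covered cholesterol and fatty acid metabolism, KLF2-linked genes, adhesion molecules, NF-kappaB, interferon, cell cycle, p53, Polycomb, HOX, YAP and SRF, coagulation, angiogenesis, endothelial identity, mesenchymal transition, oxidative, unfolded protein and heat shock responses, smooth muscle, fibroblast, blood and epithelial markers, mitochondrial and histone genes. The results of 1 list and of some named genes are not given here. KLF2 and other fixed genes are also list members. Lists were tested with camera of limma 3.58.1, which compares a list with all other genes, with a preset correlation of 0.01 and again with the correlation estimated from the data. The fry test asks whether the genes of a list move on balance one way, or in its mixed form in either direction, and compares them with no other genes. Adjustment was over the 25 lists with more than 2 measured members in each comparison.

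With the preset correlation camera called 10, 10 and 11 lists in the 3 comparisons, and with an estimated correlation 2, 1 and 6. Fold changes against a group with 1 to 3 counts are given as a ratio with an exact counting interval, and against 0 counts as a lower bound. After the data were seen, symbol families of at least 10 tested genes (170) were compared with the remaining genes by one-sided Fisher's exact tests, adjusted over 340 tests per comparison. Coordinates are from GENCODE 44 on GRCh38, a later annotation than that of the counts on the same assembly, and 231 of 233 named genes had a match.

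The fit was tested on simulated counts for 15018 genes with 200 changed. In the simvastatin comparison it recovered 56%, 84%, 88% and 90% of genes changed 1.25, 1.5, 2 and 4-fold with 8 false calls, and in the EZH2 comparison 60%, 72%, 92% and 94% with 16. Far fewer genes were changed there than the 9498 called with simvastatin, and as many up as down. The scaling was therefore not tested for changes of that extent. Alternatives were DESeq2 1.42.0, limma-voom, other scaling and filters, leaving out EZH2, the replicate number as a block, only the 6 libraries compared, each library left out, stricter thresholds and other list tests. Figures were drawn with matplotlib 3.10.9.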

Results

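RNA was sequenced from human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein, used at passage 3 to 5. EZH2 is the histone methyltransferase of the Polycomb repressive complex PRC2. Simvastatin is a statin, a drug that lowers cholesterol. Cultures first received a control adenovirus or an adenovirus carrying EZH2, and 24 h later either vehicle or 1 µM simvastatin for 48 h. There were 3 groups of 3 libraries: control virus with vehicle, control virus with simvastatin, and EZH2 virus with simvastatin. The question, from the series title, is whether EZH2 carries the action of statins on endothelial transcription. A group with the EZH2 virus and vehicle was not analysed here, so the action of EZH2 without simvastatin, and the interaction of virus and drug, were not tested.

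Total counts were 23955921 to 25600730 per library with vehicle, 22544534 to 26385804 with simvastatin and 24503966 to 28590633 with the EZH2 virus. The table held 28669 gene symbols, of which 15018 passed the expression filter. The first principal component held 76.6% of the variance and set the vehicle libraries apart from the 6 simvastatin libraries, and the second held 10.6% and separated the viruses under simvastatin. The labels do not say that the 3 libraries of a group came from separate cultures or donors. The p-values therefore measure only the spread between these libraries, which may be technical.

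EZH2 (GRCh38 chromosome 7, 148807257 to 148884321) took 0.00234% ± 0.000204 (SD, n = 3) of the counts with vehicle and 10.9% ± 0.804 (n = 3) with the EZH2 virus. The 3 EZH2 virus libraries held 2583893, 3370644 and 2911946 counts of the gene, at 114400 CPM ± 9660, and log2 change over the control virus was 11.56 (SE 0.573, adjusted p = 3.06e-05). Its pseudogene EZH2P1 on chromosome 21 held 166, 277 and 249 counts in those libraries and 0 or 1 in every other library, a ratio of 356 with a counting interval of 98.1 to 2940, and can take reads of the EZH2 transcript. Gene counts do not separate viral from cellular EZH2 transcripts.

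Simvastatin did not change EZH2 at the threshold: 38.3 CPM ± 24.6 (SD, n = 3) against 24.3 CPM ± 2.51 with vehicle, log2 change 0.65 (SE 0.436, adjusted p = 0.245). Replicate 1 of the simvastatin group held 1630 EZH2 counts, against 642 and 686 in replicates 2 and 3 and 533, 651 and 568 with vehicle. Without that library log2 change was -0.0097 (adjusted p = 0.951), and adjusted p over all alternatives was 0.132 to 0.951. Of 28 other genes measured in the Polycomb list, which also holds the demethylase genes KDM6A and KDM6B, 5 rose and 11 fell with simvastatin. KDM6A, a demethylase that opposes EZH2, stood at -0.67 (SE 0.0524) and PHF1 at 0.49 (SE 0.0591). The Polycomb list as a whole did not stand apart from the other genes (camera adjusted p = 0.484). With the EZH2 virus 3 of these 28 genes rose and 2 fell (1 and 1 with DESeq2), among them PCGF2 at 0.26 (SE 0.0498) and CBX6 at -0.20 (SE 0.0434), with camera adjusted p = 0.563.

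**Figure D1:**
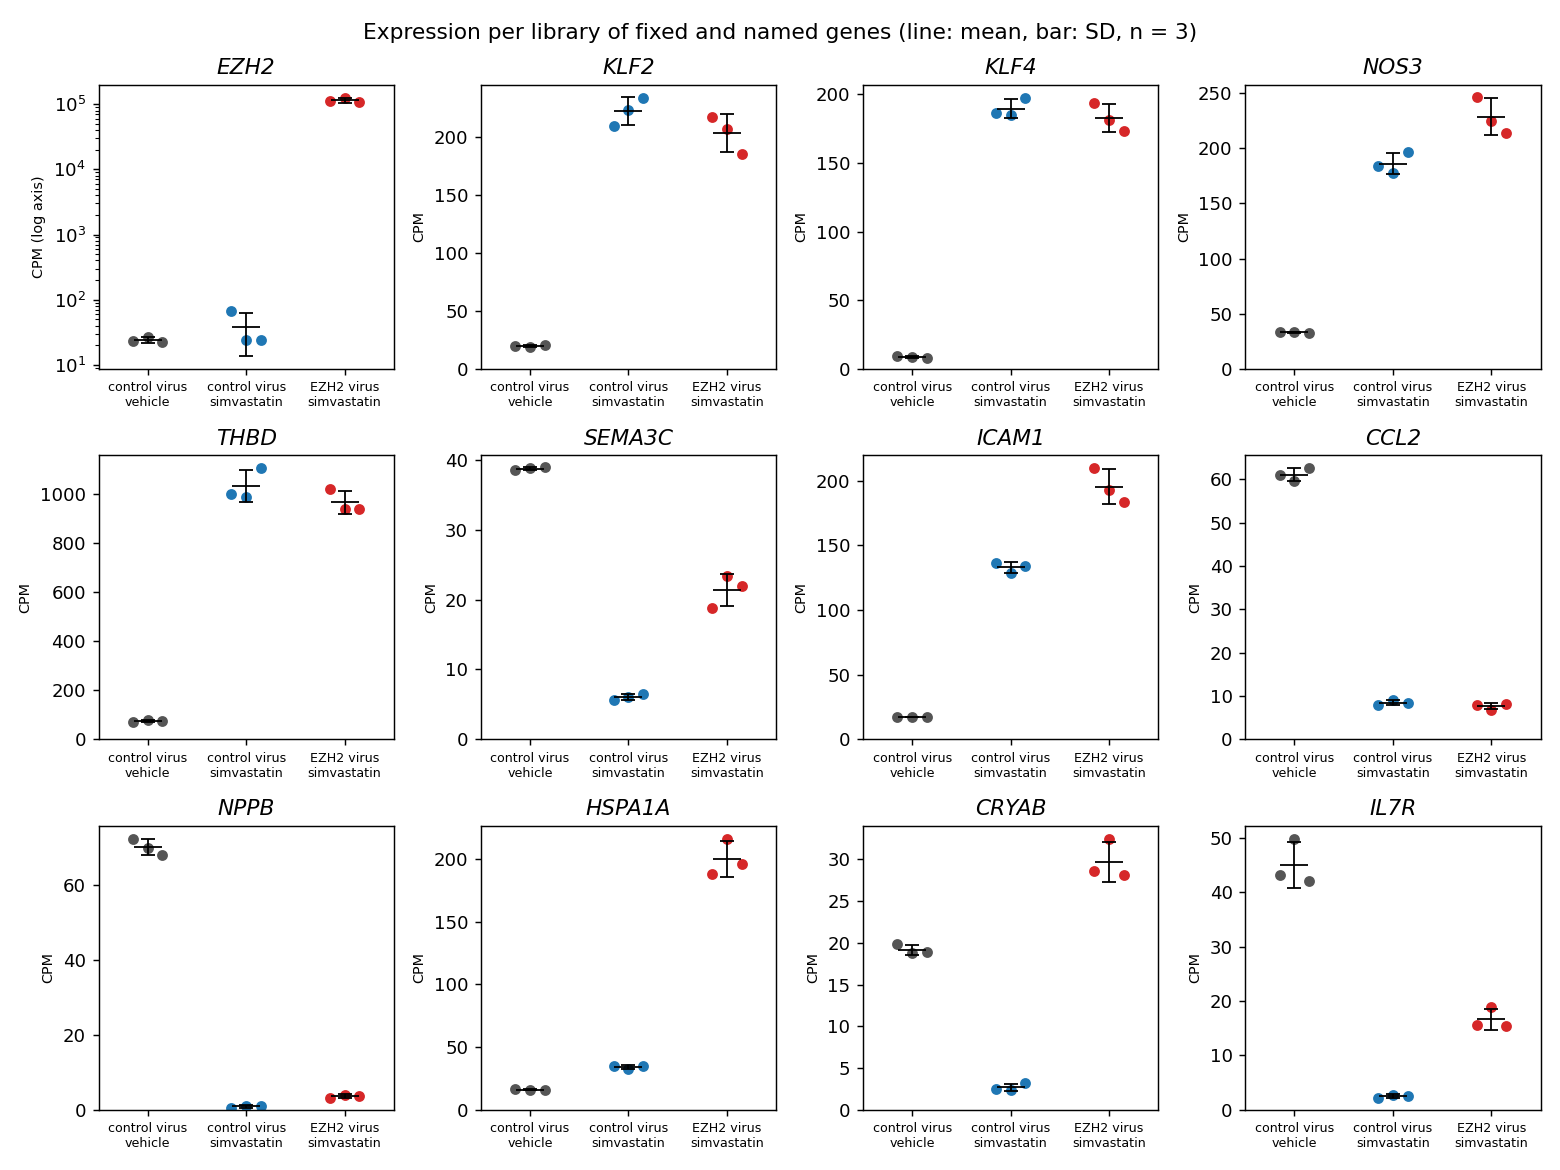
CPM of 12 genes in each library, with 1 point per library, the group mean as a line and the SD as a bar (n = 3); the vertical axis is logarithmic for EZH2 alone. KLF2 lies at 19.6 CPM with vehicle, 223 with simvastatin and 204 with the EZH2 virus, while CRYAB lies at 19.2, 2.70 and 29.7 CPM.

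The first comparison asked what simvastatin does to control-virus cells. KLF2 and KLF4, transcription factors of the quiescent endothelium, rose from 19.6 CPM ± 0.941 to 223 CPM ± 11.9 and from 8.51 CPM ± 0.614 to 190 CPM ± 6.77 (SD, n = 3 per group). Log2 changes were 3.51 (SE 0.0626, adjusted p = 7.76e-23) and 4.48 (SE 0.0615, adjusted p = 7.39e-27). Thrombomodulin (THBD), an anticoagulant surface receptor, rose from 75.03 to 1031 CPM, at log2 3.78 (SE 0.0534), and the endothelial nitric oxide synthase NOS3 from 33.2 to 186 CPM, at 2.49 (SE 0.0542). Of 15018 genes tested, 9498 (63.2%) were called, 4822 higher and 4676 lower, and 1133 and 1038 of these differed by 2-fold or more. KLF2 lies on chromosome 19 at 16324826 to 16328685, NOS3 on chromosome 7 at 150991017 to 151014588 and THBD on chromosome 20 at 23045633 to 23049672.

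Of the 19 measured genes of the KLF2-linked vasoprotective list, 16 rose and 2 fell, with a median log2 change of 2.05. Heme oxygenase HMOX1 rose from 19.6 to 349 CPM, at 4.16 (SE 0.0603), and the angiopoietin receptor TEK from 136 to 669 CPM, at 2.30 (SE 0.0430). The list stood apart from the other genes (camera adjusted p = 1.7e-34) and held with an estimated correlation (adjusted p = 0.00854). In the cholesterol synthesis and uptake list 24 of 26 genes rose, with a median of 1.04. The synthase gene HMGCS1 rose from 30.7 to 123 CPM (log2 2.004, SE 0.0466), INSIG1 from 22.0 to 95.6 CPM (2.12, SE 0.0495) and MSMO1 from 46.3 to 159 CPM (1.78, SE 0.0434). Its camera call (adjusted p = 4.11e-19) was lost with adjusted p = 0.0769 with an estimated correlation. For fatty acid synthesis and LXR targets 10 of 15 rose and 4 fell, with FADS2 at 1.92 (SE 0.0562) and MYLIP at -1.16 (SE 0.0587), and camera gave adjusted p = 0.0554. Without replicates 1, 2 and 3 of the simvastatin group in turn that value was 0.0327, 0.0303 and 0.0489, in a range over alternatives of 0.0139 to 0.105.

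Of 23 YAP and SRF target genes 20 fell and 2 rose, with a median of -1.16: the matrix protein gene THBS1 fell from 12640 CPM ± 788 to 1906 CPM ± 20 (log2 -2.73, SE 0.0476) and tropomyosin TPM1 from 1681 to 291 CPM (-2.53, SE 0.0541). That camera call (adjusted p = 2.81e-24) was lost with adjusted p = 0.0602 with an estimated correlation. In the list of endothelial-mesenchymal transition and matrix genes 19 of 24 fell and 4 rose, median -0.76, led by TGFB2 from 472 to 41.1 CPM (-3.52, SE 0.0550) and N-cadherin CDH2 (-1.67, SE 0.0432). Camera called it at adjusted p = 2.32e-09, against adjusted p = 0.0602 with an estimated correlation. Smooth muscle and pericyte markers fell in 7 of 11 cases and rose in 1, or 2 with limma-voom. The calponin gene CNN1 went from 45.0 CPM ± 3.32 to 0.929 CPM ± 0.0251 (-5.59, SE 0.117) and ACTA2 from 16.2 to 3.66 CPM (-2.15, SE 0.108). This list held with both correlations (camera adjusted p = 3.97e-06, and adjusted p = 0.0266 with an estimated correlation).

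Adhesion molecule and chemokine genes changed in both directions. ICAM1, a leukocyte adhesion molecule, rose from 17.3 to 133 CPM (2.94, SE 0.0559) and E-selectin SELE from 1.40 CPM ± 0.244 to 6.54 CPM ± 1.86 (2.22, SE 0.336, adjusted p = 0.000453), while the chemokine gene CCL2 fell from 61.1 to 8.42 CPM (-2.86, SE 0.0674) and CXCL12 from 6.25 to 0.312 CPM (-4.30, SE 0.230). VCAM1 stood at 2.33 against 1.91 CPM, log2 0.29 (SE 0.184, adjusted p = 0.182, range over alternatives 0.0352 to 0.431). Without replicate 3 of the simvastatin group the VCAM1 change was 0.46 (adjusted p = 0.0352). In the list of endothelial adhesion molecules and chemokines 5 of 17 rose and 10 fell (camera adjusted p = 0.399). Of 16 NF-kappaB feedback and signalling genes 9 rose and 4 fell, with BIRC3 at 3.26 (SE 0.168) and TNFAIP3 at -0.86 (SE 0.0558). Its camera call (adjusted p = 0.0359) was lost with adjusted p = 0.415 with an estimated correlation. It stood at 0.0515 with DESeq2, 0.0538 with limma-voom and 0.0561 with a stricter filter, in a range over alternatives of 0.00942 to 0.0561. Interferon-stimulated genes rose in 13 and fell in 6 of 25 cases, with OAS1 at 2.02 (SE 0.0986) and DDX58 at -1.18 (SE 0.0643), and camera adjusted p was 0.381.

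Genes of coagulation, angiogenesis and endothelial identity changed in both directions, and camera called none of these lists. The plasminogen activator PLAT rose from 38.5 to 390 CPM (3.34, SE 0.0578), in a coagulation and fibrinolysis list with 5 of 16 genes higher and 8 lower (camera adjusted p = 0.399). The apelin receptor APLNR rose from 17.9 to 276 CPM (3.94, SE 0.0631) and VEGFC fell from 80.3 to 27.3 CPM (-1.56, SE 0.0591). The angiogenesis and Notch list had 13 of 27 higher and 12 lower, with a median of 0.12, a mean of -0.15 and a camera direction downward that was not called (adjusted p = 0.848). Among 22 endothelial identity genes 10 rose and 8 fell, with the lymphatic marker LYVE1 at 3.80 (SE 0.0735), CD34 at 2.19 (SE 0.0495) and ENG at -0.90 (SE 0.0379), and camera gave adjusted p = 0.12. HOX genes rose in 2 and fell in 9 of 27 cases (5 with DESeq2), HOXA10 by -0.62 (SE 0.0820), without a camera call (adjusted p = 0.513).

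Most genes of the unfolded protein and oxidative stress lists rose, while the cell cycle lists were not called. Of 23 unfolded protein and integrated stress response genes 18 rose and 1 fell, median 0.62: HERPUD1 went from 74.7 to 271 CPM (1.86, SE 0.0455) and TRIB3 from 26.0 to 112 CPM (2.11, SE 0.0643). Camera called the list at adjusted p = 5.56e-09, but it stood at adjusted p = 0.12 with an estimated correlation. Of 19 oxidative stress (NRF2) genes 14 rose and 1 fell, with OSGIN1 at 2.18 (SE 0.119) and GCLM at 1.19 (SE 0.0626). That call (camera adjusted p = 0.00108) was lost with adjusted p = 0.329 with an estimated correlation. Heat shock genes rose in 7 and fell in 3 of 14 cases (camera adjusted p = 0.618), DNA replication and S phase genes rose in 13 and fell in 6 of 30 (0.484) and mitosis genes rose in 9 and fell in 4 of 29 (0.812), with 2 lower by DESeq2. CDT1, a replication licensing factor, rose by 2.11 (SE 0.182), and PCNA fell by 0.60 (SE 0.0471). Among CDK inhibitors and p53 targets 5 of 24 rose, or 3 with RLE or upper-quartile scaling or with DESeq2, and 11 fell (camera adjusted p = 0.0554), with CDKN2B at -1.74 (SE 0.0662) and CDKN1A from 392 to 299 CPM (-0.39, SE 0.0421). The camera value of that list was 0.0489 without replicate 3 of the simvastatin group, 0.0404 without replicate 1 of the vehicle group and 0.0425 without replicate 3 of the EZH2 virus group, in a range over alternatives of 0.0171 to 0.0868. Replication-dependent histone genes rose in 2 (1 with DESeq2) and fell in 5 of 10 cases (adjusted p = 0.513), and of 15 mitochondrially encoded genes MT-ND4L fell (-0.53, SE 0.18, adjusted p = 0.0397) and 0 rose (camera adjusted p = 0.513). DESeq2 called 2 of the 15 lower and limma-voom 1, with 0 higher by either and 0 higher at an unadjusted p under 0.05. The MT-ND4L value, from a gene that overlaps MT-ND4, was 0.0657 without replicate 1 of the simvastatin group and 0.0968 and 0.125 without replicates 1 and 3 of the vehicle group. It was 0.0586, 0.0629 and 0.0621 without replicates 1, 2 and 3 of the EZH2 virus group. With the replicate number as a block it was 0.0854, with only the 6 libraries compared 0.095 and without a filter 0.0806. The range over alternatives was 0.00823 to 0.125.

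Of 8 fibroblast markers 5 fell and 1 rose (camera adjusted p = 0.0474, and adjusted p = 0.386 with an estimated correlation), with periostin POSTN from 1115 to 192 CPM (-2.54, SE 0.0403) and THY1 from 0.377 to 2.70 CPM (2.83, SE 0.235). The camera value of the fibroblast list was 0.0728 without replicate 2 of the simvastatin group, 0.0567 without replicate 1 of the vehicle group, and 0.0533 and 0.0559 without replicates 1 and 2 of the EZH2 virus group. With the replicate number as a block it was 0.0519, with only the 6 libraries compared 0.0666, with a stricter filter 0.0642 and without a filter 0.0831. The range over alternatives was 0.00235 to 0.0831. Of 6 epithelial markers 3 fell and 1 rose (camera adjusted p = 0.00532, and adjusted p = 0.0979 with an estimated correlation), with KRT7 from 287 to 22.9 CPM (-3.64, SE 0.125). Of the blood cell markers CD14 and FCER1G passed the filter, and CD14 rose from 0.403 to 0.768 CPM (0.92, SE 0.308, adjusted p = 0.0113). Without replicate 2 of the simvastatin group the CD14 change was 0.71 (adjusted p = 0.0784, range over alternatives 0.0082 to 0.0784). Counts of called members adjusted over the list alone equalled those over all genes, except 14 higher for DNA replication, 2 lower for mitosis, 8 lower for HOX genes, 14 higher for angiogenesis and Notch, 15 higher for oxidative stress, 2 higher for smooth muscle and 0 lower for mitochondrial genes.

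Among the largest increases were those in PI16 (chromosome 6, 36948263 to 36964837), from 0.599 CPM ± 0.106 to 631 CPM ± 14.7 (log2 10.04, SE 0.0849), OR51E1 (8.82, SE 0.139) and NOV (8.26, SE 0.166). S100P, WNT9B, SMTNL2 and MUC5AC held 1 to 3 counts in all vehicle libraries together, with ratios of 813 (counting interval 278 to 3940), 754 (135 to 29800), 193 (65.6 to 936) and 218 (38.7 to 8630). MUC5AC belongs to a mucin family with similar repeats, so its value is uncertain. The natriuretic peptide gene NPPB (chromosome 1, 11857464 to 11858945) fell from 70.0 CPM ± 2.13 to 0.904 CPM ± 0.325 (-6.25, SE 0.110), followed by CNN1, PLN (-5.23, SE 0.266), GPRIN3 (-5.06, SE 0.406), KIT (-4.96, SE 0.166) and SLC7A14 (-4.43, SE 0.197). Cardiac actin ACTC1 fell with a ratio of 340 (60.5 to 13500). PVRL3-AS1 (-4.60, SE 0.245) is named as an antisense transcript, and it shares no exon with another gene in the annotation used.

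**Figure D2:**
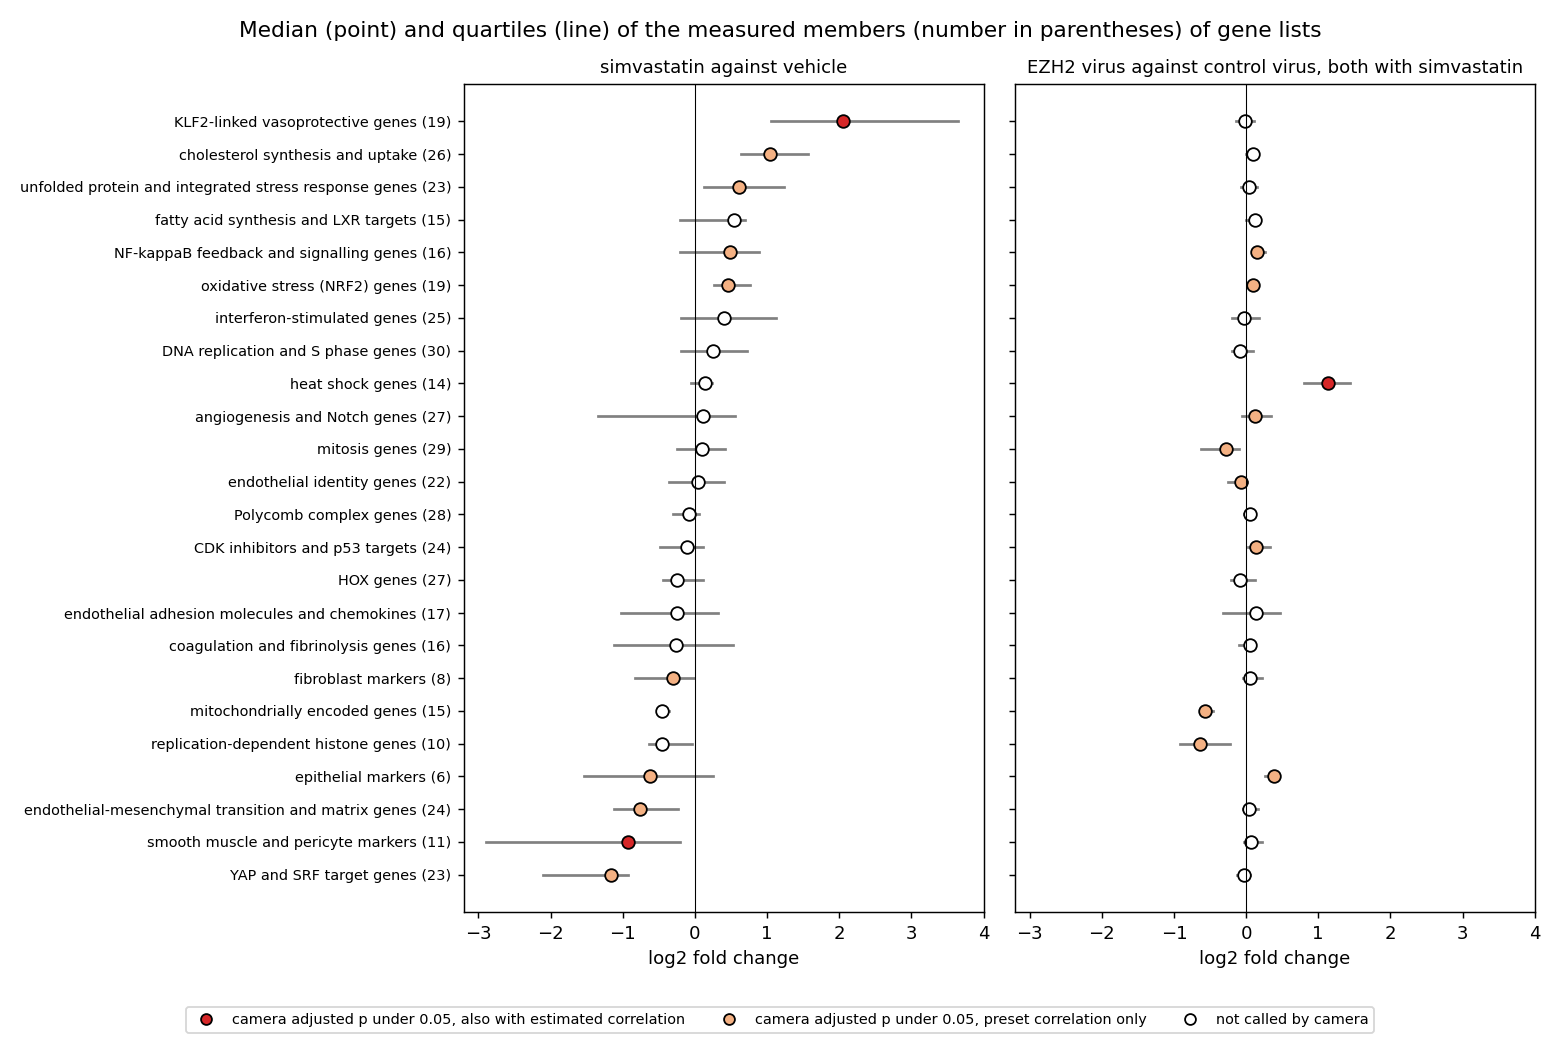
Median log2 fold change of gene lists (point) with the quartiles of its measured members (line), for simvastatin against vehicle on the left and the EZH2 virus against the control virus on the right; the number of measured genes stands in parentheses and the fill gives the camera result. The KLF2-linked list lies at a median of 2.05 on the left and -0.012 on the right, and the heat shock list at 0.14 and 1.13.

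The second comparison asked what the EZH2 virus does in simvastatin-treated cells. The 4 KLF2-linked genes fixed by name differed little between the viruses: KLF2 stood at 204 CPM ± 16.5 against 223 CPM ± 11.9 (SD, n = 3; log2 -0.13, SE 0.0517, adjusted p = 0.0811), KLF4 at 182.7 against 190 CPM (-0.05, SE 0.0456, adjusted p = 0.442) and THBD at 965 against 1031 CPM (-0.10, SE 0.0466, adjusted p = 0.152). NOS3 rose from 186 to 229 CPM (0.29, SE 0.0478, adjusted p = 7.12e-05). Every one of 14 heat shock genes rose, with a median of 1.13. ICAM1 rose from 133 to 195 CPM (0.55, SE 0.0461) and the CDK inhibitor gene CDKN1A from 299 to 432 CPM (0.53, SE 0.0421, adjusted p = 9.72e-10). In all 3236 of 15018 genes (21.5%) were called, 1846 higher and 1390 lower, at a median absolute log2 change of 0.28, and 159 and 180 of them by 2-fold or more. With upper-quartile scaling the share of higher calls was 45.9%, against 57.0% with the scaling used throughout. It was 51.7% with EZH2 left out, 53.5% with only the 6 libraries compared and 61% with DESeq2, so it depends on the processing. The KLF2 difference passed the threshold with upper-quartile scaling (-0.15, adjusted p = 0.0309), with EZH2 left out (0.0493), and with EZH2, EZH2P1 and the mitochondrial genes left out (0.0479). It also passed without replicate 1 of the simvastatin group (-0.17, adjusted p = 0.0311) or replicate 1 of the EZH2 virus group (-0.18, adjusted p = 0.0269), in a range over alternatives of 0.0269 to 0.414.

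Of the other genes fixed by name, CCL2 stood at -0.13 (SE 0.0872, adjusted p = 0.306) and VCAM1 at 0.21 (SE 0.17, adjusted p = 0.408). SELE stood at 10.98 against 6.54 CPM (0.74, SE 0.23, adjusted p = 0.0553). SELE was called without replicates 1 and 2 of the simvastatin group (0.0229 and 0.0294) or replicate 2 of the EZH2 virus group (0.0328), with DESeq2 (0.00159), with the replicate number as a block (0.000233) and without a filter (2.51e-05), in a range of 2.51e-05 to 0.145.

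Among the heat shock genes, HSPA1A rose from 34.1 CPM ± 1.29 to 200 CPM ± 14.6 (2.56, SE 0.0529), HSPA1B from 38.1 to 125 CPM (1.71, SE 0.0477), the co-chaperone DNAJB1 from 93.9 to 267 CPM (1.51, SE 0.0452) and the small heat shock protein CRYAB from 2.70 to 29.7 CPM (3.45, SE 0.0974). HSPA1A and HSPA1B are near-identical copies whose reads can be split between them. HSPA6, an inducible member outside the list (chromosome 1, 161524540 to 161526894), rose from 0.260 CPM ± 0.0777 to 45.0 CPM ± 4.50 (7.39, SE 0.147) and is also close in sequence to a pseudogene. The list stood apart from other genes with either correlation (camera adjusted p = 3.25e-173, and adjusted p = 0.00047 with an estimated correlation). The unfolded protein and integrated stress response list had 7 of 23 higher and 3 lower at a median of 0.047 (camera adjusted p = 0.236).

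**Figure D3:**
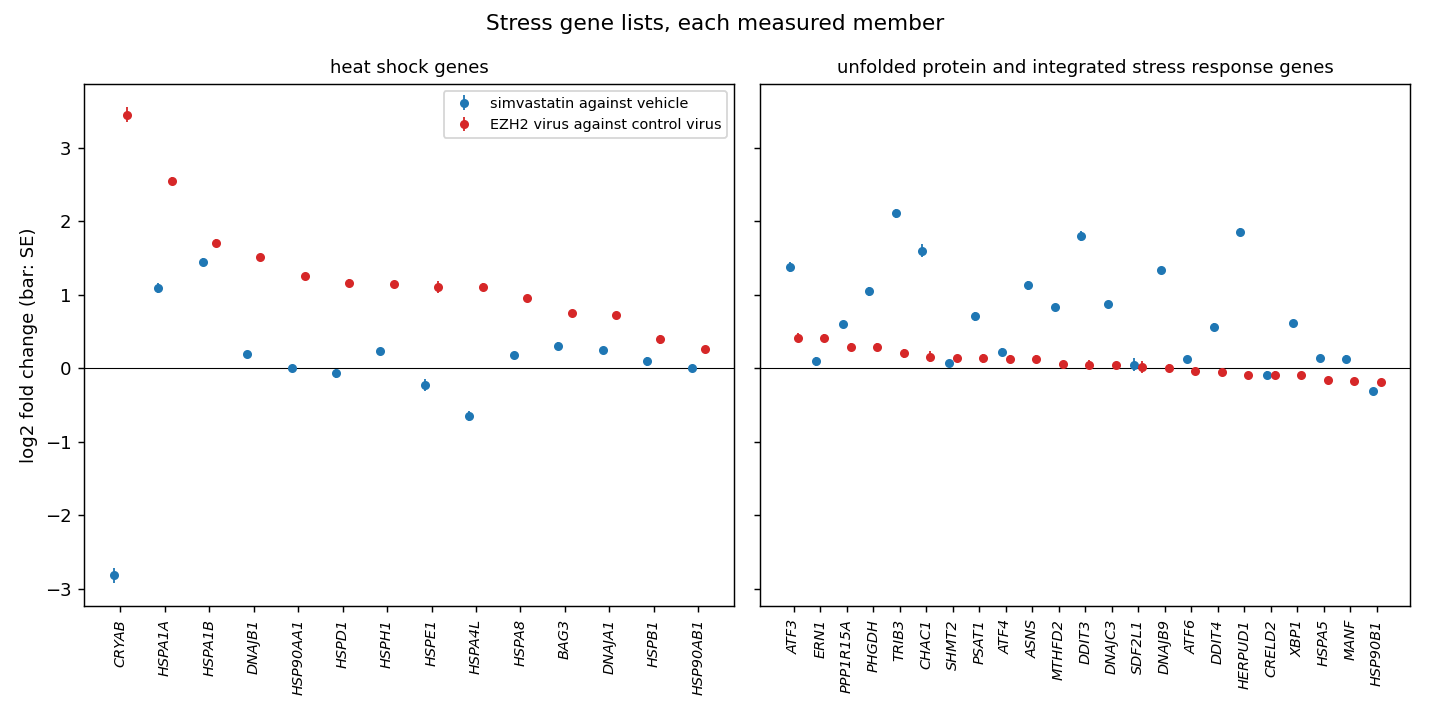
Log2 fold change (vertical axis, bar: SE) of each measured member of both stress gene lists, for simvastatin against vehicle and for the EZH2 virus against the control virus. All 14 heat shock genes lie above 0 with the EZH2 virus, with a median of 1.13, against 0.047 for the other list.

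Some mitosis and histone genes fell with the EZH2 virus, and some cell cycle inhibitor genes rose. Of 29 mitosis genes 8 fell with edgeR and 4 with DESeq2, median -0.27, with TOP2A from 15.4 to 11.4 CPM (-0.43, SE 0.0863), CDK1 (-0.69, SE 0.153) and MKI67 (-0.65, SE 0.154). That camera call (adjusted p = 0.00076) was lost with adjusted p = 0.443 with an estimated correlation. Replication-dependent histone genes fell in 7 of 10 cases, with HIST1H4H from 5.74 to 2.004 CPM (-1.52, SE 0.151) and HIST2H2BE from 8.49 to 4.36 CPM (-0.96, SE 0.117); camera gave adjusted p = 8.1e-08, and adjusted p = 0.12 with an estimated correlation. Histone genes have near-identical copies, so single members are uncertain. The libraries were made from poly(A) RNA, so transcripts without a poly(A) tail may be missed, and total histone RNA was not measured. Of 24 CDK inhibitors and p53 targets 10 rose and 1 fell, among them CDKN2B from 15.7 to 24.6 CPM (0.65, SE 0.0709), MDM2 (0.30, SE 0.0426) and FAS (0.39, SE 0.0658), at camera adjusted p = 0.000199, and adjusted p = 0.301 with an estimated correlation. DNA replication and S phase genes fell in 5 (3 with DESeq2) and rose in 1 of 30 cases (camera adjusted p = 0.217), with RRM2 from 5.75 to 2.37 CPM (-1.27, SE 0.141).

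Part of the endothelial identity, angiogenesis, NF-kappaB and oxidative stress genes were called with the EZH2 virus. Of 22 endothelial identity genes 9 fell and 2 rose: CD34 went from 218 CPM ± 7.33 to 128 CPM ± 8.57 (-0.77, SE 0.0459), LYVE1 from 60.1 to 47.3 CPM (-0.35, SE 0.0513) and ENG from 397 to 479 CPM (0.27, SE 0.0378). Camera called this list downward (adjusted p = 0.00548), and the call was lost with adjusted p = 0.301 with an estimated correlation. In the angiogenesis and Notch list 9 of 27 rose and 2 fell, with VEGFC from 27.3 to 45.6 CPM (0.74, SE 0.0610), FLT4 at 0.60 (SE 0.0739) and APLN at -0.50 (SE 0.0485), at camera adjusted p = 0.016, and adjusted p = 0.443 with an estimated correlation. Without replicate 1 of the EZH2 virus group this list had camera adjusted p = 0.0621, in a range over alternatives of 0.00129 to 0.0621. NF-kappaB genes rose in 6 of 16 cases, with TRAF2 at 0.41 (SE 0.0864) and NFKBIA at 0.27 (SE 0.0634), at camera adjusted p = 0.0252, and adjusted p = 0.462 with an estimated correlation. Without replicate 1 of the EZH2 virus group that value was 0.103 (range 9.08e-05 to 0.103). Of 19 oxidative stress genes 7 rose, or 4 with upper-quartile scaling (camera adjusted p = 0.0352, and adjusted p = 0.605 with an estimated correlation), with PRDX1 at 0.24 (SE 0.0380). Their camera adjusted p was 0.202 without replicate 1 of the EZH2 virus group and 0.0564 without replicate 1 of the simvastatin group (range 0.000362 to 0.202).

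Of 6 epithelial markers 3 rose, or 1 with upper-quartile scaling. They were KRT18 from 44.2 to 72.5 CPM (0.72, SE 0.0495), which shares 17.1% of its exon bases with KRT8, KRT7 (0.46, SE 0.134, adjusted p = 0.0478) and KRT8 (0.24, SE 0.0776, adjusted p = 0.0302). KRT7 stood at 0.0629 with upper-quartile scaling, 0.0779 without replicate 3 of the simvastatin group, 0.0668, 0.0759 and 0.0725 without replicates 1, 2 and 3 of the vehicle group, and 0.0811 without replicate 3 of the EZH2 virus group (range over alternatives 8.1e-09 to 0.0811). KRT8 stood at 0.0554 with upper-quartile scaling, 0.0953 with DESeq2, 0.0817 and 0.106 without replicates 1 and 3 of the simvastatin group, and 0.075 and 0.128 without replicates 1 and 2 of the EZH2 virus group (range 0.0165 to 0.128). The list was called at camera adjusted p = 0.00257, and adjusted p = 0.153 with an estimated correlation. Of 15 mitochondrially encoded genes edgeR called 0, at a median of -0.56, with 8 lower and 0 higher at an unadjusted p under 0.05. DESeq2 called 7 lower and limma-voom 0. Camera gave adjusted p = 0.00257, and adjusted p = 0.638 with an estimated correlation, while MT-ND1 stood at 297 CPM ± 15.3 against 490 CPM ± 129 (-0.72, SE 0.224, adjusted p = 0.0702). DESeq2 gave adjusted p = 0.00916 for MT-ND1, and the range over alternatives was 0.00816 to 0.181. Without replicate 3 of the simvastatin group edgeR called MT-ND1 (0.00816), MT-CO1 (0.000553), MT-CO3 (0.00241) and MT-ND5 (0.00423). Mitochondrial genes took 0.782% ± 0.0764 of counts with the EZH2 virus and 1.26% ± 0.326 with the control virus under simvastatin (n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

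The lists below were not called by camera. Adjusted p was 0.095 for cholesterol synthesis and uptake (8 of 26 higher), 0.251 for fatty acid synthesis and LXR targets (6 of 15 higher), 0.92 for the KLF2-linked genes (4 higher and 3 lower of 19), 0.824 for adhesion molecules and chemokines (3 and 3 of 17) and 0.79 for interferon-stimulated genes (4 and 4 of 25). The KLF2-linked list had a median of -0.012 and a mean of -0.0080 with an upward camera direction, and the interferon list a median of -0.025 and a mean of 0.0031 with a downward one. DESeq2 called 5 cholesterol genes higher, and 1 fatty acid gene, 2 interferon-stimulated genes and 2 HOX genes lower. With upper-quartile scaling 5 cholesterol genes and 2 fatty acid genes were higher, and 5 KLF2-linked genes were lower. Camera called the cholesterol list without replicates 2 and 3 of the simvastatin group (0.0363 and 0.0269), and the fatty acid list without replicate 3 (0.0426), in ranges over alternatives of 0.00154 to 0.471 and 0.0235 to 0.407. Adjusted p was 0.355 for HOX genes (1 and 4 of 27), 0.392 for YAP and SRF targets (4 of 23 lower), 0.563 for coagulation and fibrinolysis (2 and 2 of 16) and 0.575 for endothelial-mesenchymal transition and matrix genes (7 and 2 of 24). For smooth muscle markers it was 0.355 (1 of 11 higher) and for fibroblast markers 0.63 (1 of 8 higher). Within these lists, the prostacyclin synthase gene PTGIS fell from 67.0 to 50.4 CPM (-0.41, SE 0.0528), PLVAP rose from 69.8 to 98.3 CPM (0.49, SE 0.0451), TIMP3 fell from 28.2 to 14.4 CPM (-0.96, SE 0.0772) and ACTA2 rose from 3.66 to 6.94 CPM (0.92, SE 0.121). CD14 rose from 0.768 to 2.53 CPM (1.72, SE 0.205). Adjusted over the list alone, counts of higher and lower members differed from those over all genes for 10 of the lists given here. They were 8 and 1 for cholesterol, 6 and 5 for KLF2-linked genes, 6 and 4 for adhesion molecules, 3 and 5 for DNA replication, 11 and 1 for CDK inhibitors and p53, and 2 and 2 for Polycomb genes. NF-kappaB had 7 higher and YAP and SRF targets 3 lower. The counts were 11 and 4 for angiogenesis and Notch, and 3 and 9 for endothelial identity.

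Outside the lists, the largest increases after EZH2, EZH2P1 and HSPA6 were in the chemokine gene CCL26 (4.51, SE 0.244), the neurotrophin receptor gene NGFR (4.06, SE 0.224), the HSP40 family member DNAJA4 (2.92, SE 0.130) and DHRS2 (2.77, SE 0.117). CCL26 went from 0.191 CPM ± 0.0807 to 4.40 CPM ± 0.439. The largest decreases were in LINC01311 (-3.59, SE 0.364), CAPN10-AS1 (-3.01, SE 0.206), C9orf163 (-2.58, SE 0.293), CCK (-2.56, SE 0.274), DMBT1 (-2.24, SE 0.238), RNF139-AS1 (-2.02, SE 0.200), OR51E1 (-1.95, SE 0.0605) and LINC01268 (-1.93, SE 0.265). CAPN10-AS1 and RNF139-AS1 are named as antisense transcripts, and they share no exon with another gene in the annotation used.

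Set against vehicle, cells with the EZH2 virus and simvastatin kept most of the simvastatin pattern. KLF2 stood at 204 against 19.6 CPM (log2 3.38, SE 0.0626), NOS3 at 229 against 33.2 CPM (2.78, SE 0.0543), THBD at 3.69 (SE 0.0532) and CCL2 at -2.99 (SE 0.0688), while CDKN1A was 0.14 higher on the log2 scale (SE 0.0419, adjusted p = 0.00579). All 26 cholesterol genes and all 14 heat shock genes rose, 21 of 23 YAP and SRF targets fell, and 16 of 19 KLF2-linked genes rose. These lists, the endothelial-mesenchymal transition list (19 of 24 lower) and smooth muscle markers (7 of 11 lower) held with an estimated correlation, with adjusted p = 0.00897 for the KLF2-linked list and 0.04 for the other 5. Of 15 mitochondrially encoded genes 13 fell, with MT-ND4 at -1.07 (SE 0.224), but camera did not call that list (adjusted p = 0.114, and adjusted p = 0.729 with an estimated correlation). Without replicate 3 of the simvastatin group, which is not part of this comparison but enters the fit, its camera value was 0.00331, and it was 0.015 in a fit of only the 6 libraries compared and 0.000384 without a filter, in a range over alternatives of 0.000384 to 0.182. Of 10 histone genes 8 fell and 1 rose. KLF4 stood at 4.43 (SE 0.0615), ICAM1 at 3.49 (SE 0.0558) and SELE at 2.96 (SE 0.311). VCAM1 stood at 0.50 (SE 0.18, adjusted p = 0.0179), but at 0.0854 with DESeq2. Its value was 0.0554 and 0.08 without replicates 2 and 3 of the vehicle group and 0.0743 without replicate 3 of the EZH2 virus group. The range over alternatives was 0.00981 to 0.0854. Camera also called the fatty acid, NF-kappaB, oxidative stress, unfolded protein and histone lists (adjusted p = 0.0205, 0.00319, 4.65e-05, 4.63e-10 and 0.0247), but not with an estimated correlation (adjusted p = 0.342, 0.223, 0.187, 0.0994 and 0.304). The endothelial identity list had a median of -0.0056, a mean of 0.17 and an upward camera direction that was not called. Adjusted over the list alone, HOX genes had 1 higher and 7 lower, against 2 and 10 over all genes (1 and 5 with DESeq2), and the other lists had equal counts. Among the largest increases after EZH2 were those in EZH2P1, PI16 (10.07, SE 0.0849), HSPA6 (8.60, SE 0.172) and NOV (8.56, SE 0.160), and the largest decreases were in PLN (-6.00, SE 0.297), CNN1 (-5.65, SE 0.119) and KIT (-5.64, SE 0.184). In total 9793 genes (65.2%) were called, 4958 higher and 4835 lower. EZH2P1, at 0 counts with vehicle, was at least 215-fold higher against a floor of 3 counts over the group.

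The 3 groups also show which genes changed by simvastatin moved toward vehicle with the EZH2 virus. Without a group of EZH2 virus and vehicle, a virus effect independent of simvastatin cannot be told apart from a reversal. The words moved back and returned therefore describe the position against vehicle, not a cause. CRYAB, lowered by simvastatin from 19.2 to 2.70 CPM, stood at 29.7 CPM with the EZH2 virus, above its vehicle level. CRYAB also belongs to the heat shock list, in which every gene rose with that virus. The interleukin-7 receptor gene IL7R went from 45.0 CPM ± 4.21 to 2.47 CPM ± 0.340 and back to 16.7 CPM ± 1.94, NPPB from 70.0 to 0.904 and 3.59 CPM, and the semaphorin gene SEMA3C from 38.7 to 6.05 and 21.4 CPM. AOX1, LIPH, ATOH8 and IL11 followed the same course, with log2 changes under the EZH2 virus of 2.67, 1.83, 1.77 and 1.60. Among genes raised by simvastatin, OR51E1 went from 0.111 to 52.2 and then 13.5 CPM ± 0.138, A2M from 5.97 to 15.2 and 5.92 CPM, and TRPV1 from 1.94 to 10.8 and 4.10 CPM. CCK, DMBT1, ADD2, MT1G and KIF1A also rose and then fell, by 2.56, 2.24, 1.60, 1.60 and 1.33 on the log2 scale.

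Of 2368 genes called in both comparisons, 1415 (59.8%) moved in opposite directions, 572 raised and then lowered and 843 lowered and then raised, and 953 moved the same way, 576 up and 377 down. Without replicate 1 of the EZH2 virus group 622 moved the same way. Independent lists of these sizes would give 446, 574, 592 and 433. Both comparisons use the same simvastatin libraries, which alone make changes point in opposite directions: 50 simulated draws with no effect gave a mean correlation across genes of -0.48. Draws without effects hold almost no called genes, so they give no expected number for the classes above. The observed correlation across 15016 genes was -0.18 and the covariance -0.067, against a simulated covariance of -0.018, a difference of -0.050. Opposite signs were found in 53.71% of these genes, against a mean of 66.4% in the draws. The variance of the simvastatin changes was 0.0369 in the draws and 0.917 in the data. Noise of the shared libraries therefore weighed far more on signs and correlations in the draws. Their share and correlation thus give no expectation for these data. Genes are not independent replicates. The 3 shared libraries cannot be split into parts of 2 libraries, so part of the excess in covariance may come from them. With the simvastatin change taken from 2 of them and the EZH2 change from the remaining library, the correlation was -0.067 to -0.14. Of genes called with simvastatin, 50.1% to 58% then had opposite signs. With the EZH2 virus libraries as the shared group instead, 1755 genes moved in opposite directions, more than the 1415 above. That count covers another class of genes, those that the EZH2 virus set apart from both other groups in 1 direction. It includes the 953 that moved the same way and genes not called with simvastatin, so it is no like measure for the 1415. Opposite directions alone do not show a return toward vehicle.

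Among the 2171 genes that simvastatin changed by 2-fold or more, the EZH2 virus called 435 (20%) back toward vehicle and 198 (9.12%) further away, and 1538 (70.8%) were not called. The median gene of this set was returned by 3.63% of its simvastatin change (quartiles -8.11% and 19.3%), and 92.7% still differed from vehicle on the same side. The 1415 oppositely called genes were returned by a median of 58.8%, a set chosen for moving back. Raised genes of 2-fold or more were called back in 15.4% of cases and lowered genes in 25.1%, a difference that was not tested.

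**Figure D4:**
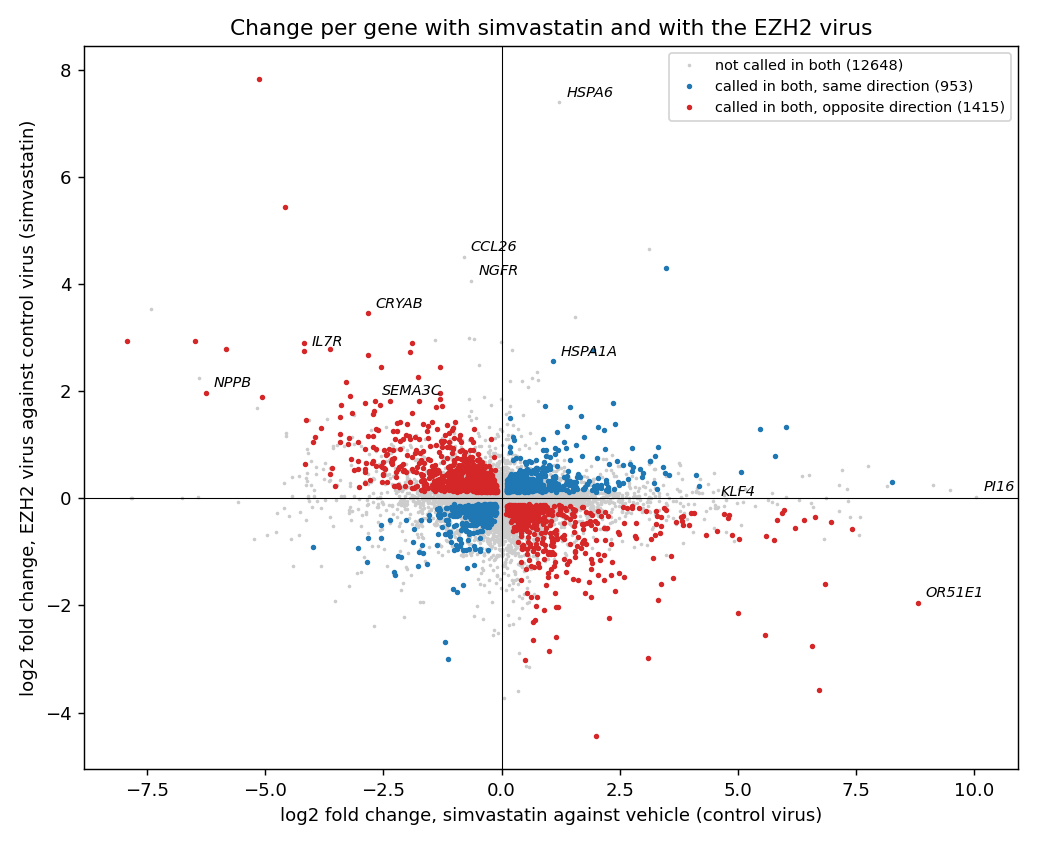
Log2 fold change of each tested gene except EZH2 and EZH2P1 with simvastatin (horizontal) and with the EZH2 virus under simvastatin (vertical), with genes called in both comparisons coloured by direction. Of the coloured genes 1415 lie in the opposite quadrants and 953 in the same-sign quadrants, and both axes share the simvastatin libraries.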

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

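Of the tests below, those that leave out the mitochondrial genes with EZH2 and EZH2P1 were chosen only after the result was seen. KLF2, SELE, VCAM1, CD14, KRT7, KRT8 and the mitochondrial genes had calls that 1 library or setting decided, with values beside them in the comparisons. No result called with the settings of the report changed its direction under the alternatives run. The epithelial list with both treatments, not called (0.0626, median -0.30), was called by DESeq2 at a median of 0.0017 (adjusted p = 0.0431). It was also called with limma-voom (0.0207), the stricter filter (0.0187), only 6 libraries (0.00974), the block (0.0282), and without simvastatin replicates 1 and 2 (0.0068 and 0.0384) or EZH2 virus replicate 2 (0.0158), in a range of 0.0068 to 0.159. The EZH2 change with simvastatin, not called, went from 0.65 to -0.0097 without replicate 1 of the simvastatin group.

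Requiring a fold change beyond 1.5 with glmTreat left 2711 genes for simvastatin (1373 higher, 1338 lower), 153 for the EZH2 virus (80 higher, 73 lower) and 2895 for both together (1508 higher, 1387 lower). With that requirement 56 genes were moved back and 8 moved the same way. At adjusted p under 0.01 the EZH2 virus called 1854 genes (1105 higher, 749 lower), with 785 moved back and 488 moved the same way. Both settings ask for more before a gene is called, so the lower counts follow from their construction. DESeq2 called 892 genes lower with the EZH2 virus, against 1390 with edgeR, and the cause was not tested.

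Leaving out each library in turn gave 8894 to 9538 genes for simvastatin (4474 to 4833 higher, 4338 to 4705 lower) and 9171 to 10050 for both together (4636 to 5082 higher, 4502 to 4970 lower). For the EZH2 virus it gave 2300 to 3273 genes (1332 to 1863 higher, 968 to 1477 lower). The moved-back count was 1006 to 1367 and the same-direction count 622 to 982, with 622 without replicate 1 of the EZH2 virus group against 953 with all libraries. Fewer libraries were fitted in each case.

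With the replicate number as a block the counts were 9430, 3086 and 9726, with 1341 moved back and 911 moved the same way. Libraries of equal number in different groups correlated at -0.0794 to 0.0586 over 9 pairs, and those of different number at -0.0938 to 0.0609 over 18 pairs, so the numbers do not pair the libraries. RLE scaling, upper-quartile scaling, limma-voom, both filters, EZH2 left out and fits of only 6 libraries kept each count within 1.5 times its value. The median log2 change of all genes lay at -0.0407 to 0.00416 with RLE and upper-quartile scaling, and at -0.00416 to 0.00932 with TMM.

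Of 75 list results, 22 calls were lost with an estimated correlation. With fry, which compares a list with no other genes, 28 more lists passed and 1 call was lost. DESeq2 ended 8 calls and added 6 among the named genes, and the libraries left out in turn ended 71 and added 15. A floor of 3 counts corresponds to 0.105 to 0.133 CPM, which limits what can be said of genes with a few counts per library.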

Other observations

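The tests of symbol families, of the unfolded protein list and of the smooth muscle markers were chosen only after the results were seen. Most symbols beginning with RPL or RPS fell with simvastatin. Of these, 56 of 72 RPL and 37 of 54 RPS symbols were called lower, at medians of -0.45 and -0.37 (one-sided Fisher's exact tests over 170 families, adjusted p = 1.44e-13 and 2.95e-06). Families were formed from symbols alone, so they can include pseudogenes, which can take reads of their parent genes. The Fisher tests treat the symbols as independent. RPL3 went from 1898 to 1351 CPM and RPS2 from 1134 to 844 CPM. The RPS symbols include the kinase genes RPS6KA3 and RPS6KA5, which rose. With the EZH2 virus, against simvastatin alone, 22 RPL and 14 RPS symbols were called lower, at medians of -0.092 and -0.0996 (adjusted p = 5.05e-05 and 0.0145), or 28 and 22 with upper-quartile scaling and 24 and 20 with EZH2 left out. Ribosomal protein genes took 4.45% ± 0.137 (SD, n = 3) of counts with vehicle, 3.75% ± 0.172 with simvastatin and 3.05% ± 0.0254 with the EZH2 virus, where EZH2 itself took part of the counts. Symbols beginning with CD were called higher with simvastatin in 25 of 41 cases (median 0.41, adjusted p = 0.015) and lower in 11, and those beginning with SLC were higher in 102 of 237 (median 0.090, adjusted p = 0.0208) and lower in 72. Of genes outside these families 32% and 31.9% were called higher.

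Most genes of the wider histone family were lower with the EZH2 virus. This family includes the 10 measured genes of the histone list, of which 7 were called lower, so it is not separate support. Of 21 HIST genes 14 were called lower, at a median of -0.80 (adjusted p = 6.75e-08), with HIST4H4 from 1.40 to 0.221 CPM and HIST1H1C from 9.86 to 5.83 CPM. Small nucleolar RNA host genes were lower in 9 of 21 cases (median -0.19, adjusted p = 0.00421), with SNHG3 from 14.3 to 7.43 CPM. Integrin alpha genes were higher in 7 of 11 cases (median 0.21, adjusted p = 0.00499), with ITGA1 from 4.34 to 8.44 CPM and ITGA2 from 55.4 to 82.6 CPM, while ITGA6 fell by 0.21 on the log2 scale. HSPA genes were higher in 9 of 17 cases (median 0.38) and ZNF genes lower in 69 of 467 (median -0.075), both with adjusted p = 0.00421. The HSPA genes include HSPA1A, HSPA1B, HSPA8 and HSPA4L of the heat shock list. Of the ZNF genes 22 were higher, and the 14.8% that were lower compare with 9.08% of other genes. The medians of these families kept their sign with RLE and upper-quartile scaling and with EZH2 left out. The histone genes took 0.00752% ± 0.000624 of counts with simvastatin and 0.00434% ± 9.76e-05 with the EZH2 virus (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). These counts come from poly(A) RNA and do not measure all histone RNA.

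Heat shock genes such as HSPA1A and DNAJB1 were higher with the EZH2 virus, at a list median of 1.13. The median was 1.114 with EZH2 left out, and 1.13 and 1.1 with RLE and upper-quartile scaling. TMM trims genes with extreme changes, so leaving out EZH2 could hardly move it and does not test for a distortion of the scaling. The list also stood apart from the other genes, which a shift of the scaling would move alike. A stress that raised unfolded protein and amino acid genes alike on top of simvastatin is argued against. That list had a median of 0.04694, a difference of 1.079 (permutation p = 1e-05, the smallest that 100000 resamples give). The permutation treats genes as independent, while estimated correlations were 0.403 within the heat shock list and 0.236 within the other. Simvastatin alone had raised 18 of the 23 unfolded protein genes, so a masked rise by the virus cannot be excluded. The lowest EZH2 virus library lay 1.206 above the highest other library in mean log2 CPM of the list, against a largest range of 0.121 within a group, so 1 library did not carry the rise. The EZH2 product and the dose and handling of its virus differ together with the group, so these stay open and were not tested.

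EZH2 in replicate 1 of the simvastatin group lay 2.77-fold over the mean of its group mates, an excess of 1.47 on the log2 scale and 1040 counts. More dividing cells are argued against, because DNA replication and S phase genes lay at -0.0418 relative to the mates, and mitosis genes at 0.205. A trace of an EZH2 virus library, 0.0352% of one, may also give such an excess. It would bring at most 0.4104 counts of any other gene that is at least 8 times higher there, in this case HSPA6, so a trace and a true difference cannot be told apart with so few counts.

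Smooth muscle markers such as CNN1, TAGLN and ACTA2 fell with simvastatin. Fewer smooth muscle cells or pericytes in the cultures could lower all of them. Of 7 markers with at least 100 counts per library 1 was not called lower, RGS5, which rose by 0.17 (adjusted p = 0.00106) from a baseline that may hide a small share of other cells. Among the rarer markers, MYH11, PDGFRB and CSPG4 held a mean of 8.33, 10 and 18.8 counts per library and were not called. LMOD1, with 33.5 counts, was called lower (-3.96), and TAGLN held 15120 counts. A fall of contractile genes within the endothelial cells, beside the YAP and SRF targets, is the alternative: 6 contractile members had a mean of -2.51 and 5 surface members -0.379, a difference of -2.128 (exact permutation p = 0.0909). These explanations cannot be told apart, since 11 genes are few and MCAM and NOTCH3, at the surface, also fell.

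For the count of changed genes, 10 splits of 6 libraries are too few for a share under 0.05, and 1 split of the 10, the real one, gave as many genes in each test. In fits of 6 libraries the real split called 9248 genes for simvastatin, 2979 for the EZH2 virus and 9881 for both together, and the highest of the other splits called 0 with edgeR, with 190, 464 and 82 genes at an unadjusted p under 0.05. The moved-back count was 1415, against 0 at the highest of the other splits. Since the other splits called 0 genes for the EZH2 virus, that 0 says nothing about moving back. With both simvastatin groups exchanged in that count, so that the EZH2 virus libraries were the shared group, 1755 genes moved in opposite directions. The labels as given are thus not the extreme assignment, although the exchanged count covers another class of genes, as stated above.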
